A study of Homo sapiens with 6 samples.

How the data were processed

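RNA was measured in MDA-MB-231, an established human cell line from a triple-negative breast cancer (a tumour type without oestrogen receptor, progesterone receptor or HER2 amplification). Per the labels' protocols, cells were exposed to PM2.5 (airborne particulate matter up to 2.5 micrometres in diameter), RNA was extracted with TRIzol after 48 h, and libraries were made with the NEBNext Ultra RNA kit and sequenced on an Illumina NovaSeq instrument. The 6 libraries fall into 2 groups of 3 by the treatment given in the labels, Control and PM2.5. The design text describes 3 biological replicates per condition but not how separate the cultures were. The p-values of single genes measure the spread between these libraries. The particle dose, the vehicle of the controls and any culture or library batch are not given in the sources used here.

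The authors deposited 1 table of raw counts per gene for the 6 libraries, per the file headers, with gene symbols, coordinates, lengths and biotypes beside the counts. The genome build is GRCh38 per the submitters' processing notes. The aligner, the counter, their versions and the strand setting are not given in the sources used here. All 58735 gene identifiers, with their chromosome, start and end, matched GENCODE release 29, which was therefore used for gene lengths, exon overlaps and GC content. Symbols are those of the deposited table, so that CTGF stands for the gene now named CCN2 and HIST1H2AC for H2AC6.

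Each column of counts was assigned to a library by its title. Total counts ran from 31846136 to 34691009 per library. A count of 0 in a library allows a level of up to 0.0865 to 0.0942 CPM (counts scaled to a common library total), which is 3 counts of that library's total. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a group differed beyond sampling noise, with a chi-square per degree of freedom between 5.85 and 36.5 for every within-group pair, so each library was kept as its own replicate.

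Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 14975 genes. Libraries were scaled by TMM factors, which ran from 0.962 to 1.047. The groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided, group as the only term) with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. Log2 fold changes are PM2.5 over Control as labelled. The standard error (SE) is the size of the log2 fold change divided by the square root of F. Levels are CPM with TMM factors, as mean ± SD over 3 libraries.

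A set of 32 gene lists was fixed from textbook knowledge before the data were examined. Of their 652 genes 650 were matched to the table, 20 of them through a current symbol. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Each list was tested again with an estimated correlation and with fry. At the preset correlation camera takes its degrees of freedom from the genes, so its p-values do not measure the spread between libraries alone. For each list the number of called members is also given adjusted over the list alone. The lists cover aryl hydrocarbon receptor, NRF2 and metal responses, heat shock, endoplasmic reticulum chaperones, ATF4, NF-kB, interferon, immediate early and p53 targets, mesenchymal and epithelial genes, matrix proteases, TGF-beta, YAP, hypoxia, glycolysis, respiration, mitochondrial, lipid, replication, mitosis, repair, histone, lysosome, ribosome, immune and stem cell genes, and markers of luminal, leukocyte and endothelial cells.

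The rule for the genes named was fixed at the same time. It took the 12 largest rises and the 12 largest falls among protein-coding genes with an adjusted p under 0.05, a mean of at least 2 CPM and no overlap between the groups. It also took the 6 smallest p-values in each direction, up to 4 called members of each list with the smallest p, and 22 genes named in any case. Any other gene is said to be chosen after its values were seen.

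The fit was tested on simulated data: counts for the 14975 genes were drawn from the libraries' means and sizes, with 200 genes changed. For PM2.5 against Control it recovered 35.8% of the genes changed 1.5-fold, 71.6% of those changed 2-fold and 93.9% of those changed 4-fold. Of its calls 5% were unchanged genes, and with no gene changed it called 0 genes and 0 lists. Each simulated gene was given the spread that edgeR's fitted trend holds for its level. No simulated library was set apart from its group, as Control replicate 3 was in the data. The data may therefore hold more false calls than the simulation. The simulated genes varied independently, whereas the estimated correlation in the data reached 0.93 for ribosomal proteins. The simulation therefore does not show how often camera at the preset correlation calls unchanged lists whose genes vary together.

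The comparison was repeated with DESeq2 size factors and upper quartile factors in the same fit, the Wald test of DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts (CPM of at least 1 in all 3 libraries of a group), a replicate block, each library left out in turn, and protein-coding genes only. After the data were seen 2 more settings were added: trends on GC content and gene length removed per library, and scaling without the 10 most abundant genes and without TMM. Figures were drawn with matplotlib 3.10.9. Without a stated strand setting, reads of antisense and overlapping genes cannot be told apart, and reads shared by near-identical copies may have been split or dropped.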

Results

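Gene expression was profiled by RNA sequencing in MDA-MB-231 breast cancer cells, to ask how exposure to PM2.5 bears on the malignant behaviour of this subtype. The data are gene counts of 6 libraries, 3 labelled Control and 3 labelled PM2.5, from RNA taken after 48 h. Total counts were 31846136, 33495707 and 32655722 in Control replicates 1 to 3 and 34555796, 32187965 and 34691009 in PM2.5 replicates 1 to 3. Because several genes known to be induced by particulate matter, such as HMOX1 and CYP1A1, were lower in the libraries labelled PM2.5, directions are given throughout for the libraries as labelled.

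Expression differed widely between the groups. Haem oxygenase 1 (HMOX1) had the smallest p-value of all genes. It fell from 813 ± 58.3 CPM in the libraries labelled Control to 51.3 ± 6.0 CPM in those labelled PM2.5 (SD, n = 3 each). The centromere chaperone HJURP had the smallest p-value among the rises, from 15.9 ± 1.59 to 122 ± 2.02 CPM. Of 14975 genes tested, 4775 changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2410 higher and 2365 lower in the libraries labelled PM2.5. A change of at least 2-fold was called for 1081 genes, 736 higher and 345 lower. The libraries of the groups did not overlap for 6636 genes, 44.3% of those tested, where chance gives 10%. Without PM2.5 replicate 1 the number of lower genes was 1448, less than the 2365 by more than 1.5 times.

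The first principal component held 56.9% of the variance and separated the groups. The second held 15% and set Control replicate 3, at a score of -36.94, apart from Control replicates 1 and 2 at 16.48 and 14.83. Correlations of log2 CPM were 0.985 to 0.990 within groups and 0.965 to 0.972 between them. Mitochondrial transcripts took 3.22% ± 0.219 of counts in the libraries labelled Control and 2.73% ± 0.0503 in those labelled PM2.5 (SD, n = 3 each).

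**Figure D1:**
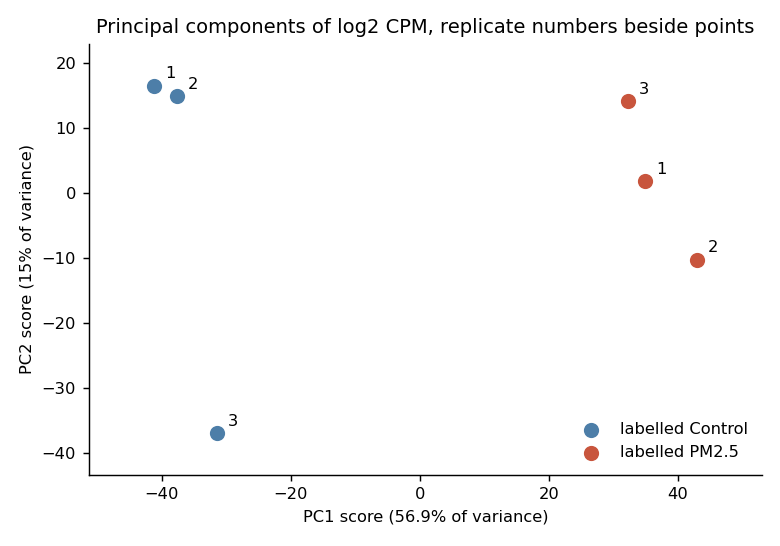
Scores of the 6 libraries on the first and second principal components of log2 CPM (axes in score units with the percent of variance), coloured by labelled group with replicate numbers beside the points. The first component separates the groups, and Control replicate 3 lies apart at -36.94 on the second.

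**Figure D2:**
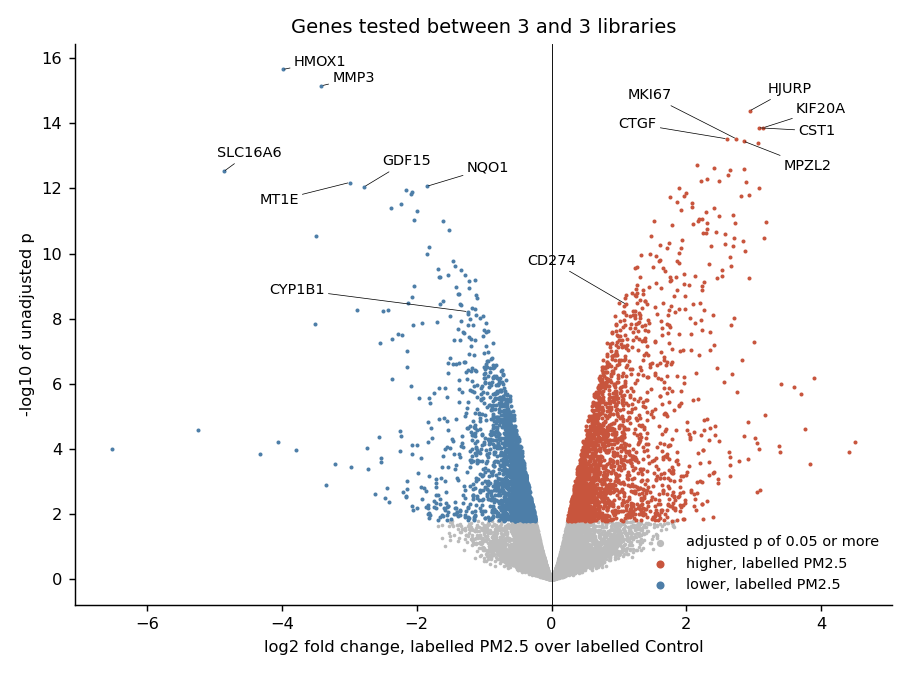
Log2 fold change (labelled PM2.5 over labelled Control, x axis) against -log10 of the unadjusted p (y axis) for the 14975 genes tested, coloured where the adjusted p was under 0.05. HMOX1 lies furthest up on the left at -3.99, and HJURP furthest up on the right at 2.94.

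Of 37 tested genes of the xenobiotic, oxidative and metal responses 22 were lower and 3 higher in the libraries labelled PM2.5. HMOX1, which degrades haem, lies on chromosome 22 at 35380361 to 35394214 on the plus strand (GRCh38, ENSG00000100292) and fell 15.8-fold, with a log2 change of -3.99 ± 0.12 (SE, n = 3 each, adjusted p = 3.36e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). NQO1, a quinone reductase on chromosome 16 at 69706996 to 69726951 on the minus strand (ENSG00000181019), fell 3.60-fold from 262 ± 13.8 to 72.9 ± 2.95 CPM. CYP1A1, the classic cytochrome P450 target of the aryl hydrocarbon receptor, on chromosome 15 at 74719542 to 74725610 on the minus strand (ENSG00000140465), fell 2.30-fold from 6.29 ± 1.73 to 2.73 ± 0.65 CPM, and CYP1B1 fell 2.37-fold from 533 ± 54.7 to 226 ± 28.7 CPM. The zinc-binding metallothionein MT1E fell 7.98-fold, from 279 ± 66.1 to 34.97 ± 1.99 CPM.

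Among 10 tested aryl hydrocarbon receptor targets 6 fell and 1 rose, and adjusted over the list alone 7 fell and 2 rose. SERPINB2, a protease inhibitor, fell by 2.07 ± 0.11 on the log2 scale and TIPARP, a feedback ADP-ribosyltransferase, by 0.38 ± 0.11, while the amino acid transporter SLC7A5 rose by 0.75 ± 0.09 and the receptor's repressor AHRR did not pass the test (log2 change -0.26 ± 0.26, SE). The TIPARP call was lost without Control replicate 2 (adjusted p = 0.0912), PM2.5 replicate 1 (0.0908) or PM2.5 replicate 3 (0.0566) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The list as a whole was lower by camera (median log2 change -0.89, or -0.57 with the stricter filter on low counts, adjusted p = 1.24e-06; adjusted p = 0.037 with an estimated correlation).

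The NRF2 antioxidant list was lower as well (median -0.46, adjusted p = 5.88e-17 by camera; adjusted p = 0.026 with an estimated correlation), with 13 of 23 tested members lower and 1 higher, and 15 and 1 adjusted over the list alone. The iron storage chains FTH1 and FTL fell by 2.03 ± 0.12 and 1.61 ± 0.14 on the log2 scale, and GCLM, a subunit of the enzyme that starts glutathione synthesis, by 1.02 ± 0.09. Of 5 tested metallothionein and metal response genes 4 fell and 1 rose, with the same numbers adjusted over the list alone (median -1.70, adjusted p = 2.36e-12 by camera; adjusted p = 0.043 with an estimated correlation). MT1X, MT2A and the zinc exporter SLC30A1 fell by 2.39 ± 0.13, 1.34 ± 0.13 and 1.70 ± 0.16. Metallothioneins and FTH1 share sequence with near-identical copies, and other genes' exons cover 62.4% of FTH1's exonic bases, so the level of each single copy is uncertain.

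**Figure D3:**
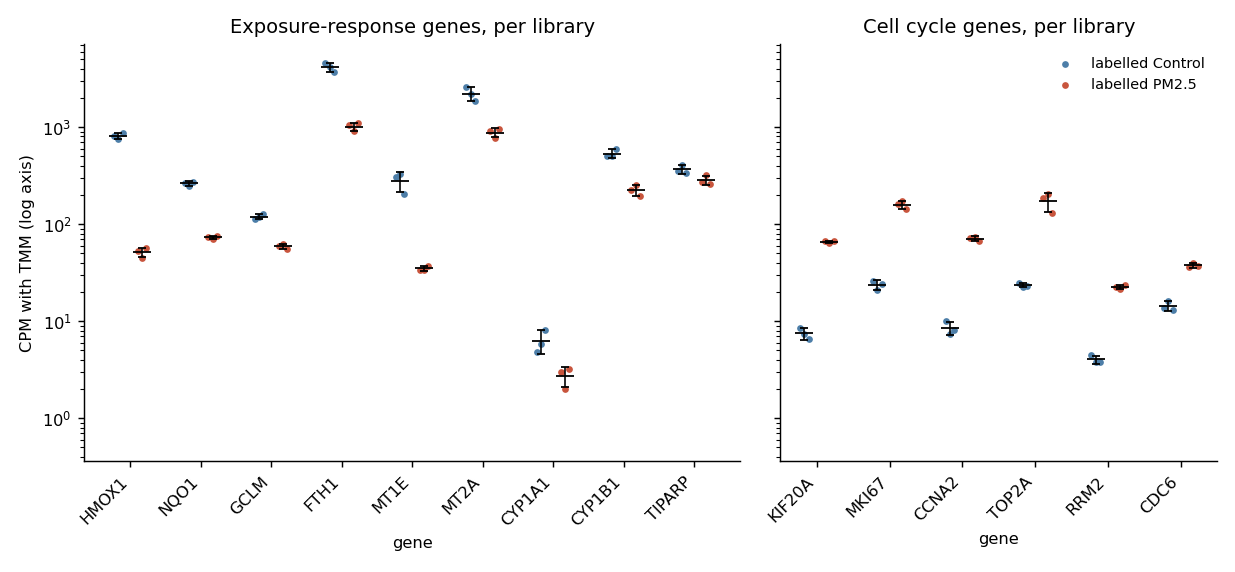
CPM with TMM factors (log axis) of exposure-response genes (left) and cell cycle genes (right) in each library, with bars for the mean ± SD of 3 libraries per labelled group. HMOX1 lay near 813 CPM in the libraries labelled Control and 51.3 CPM in those labelled PM2.5, and MKI67 near 23.7 and 158 CPM.

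Of 30 tested G2/M and mitosis genes 29 rose and 0 fell. The proliferation marker MKI67, on chromosome 10 at 128096659 to 128126385 on the minus strand (ENSG00000148773), rose 6.68-fold from 23.7 ± 2.57 to 158 ± 13.7 CPM (log2 change 2.74 ± 0.11, SE, n = 3 each, adjusted p = 6.47e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The mitotic kinesin KIF20A, on chromosome 5 at 138178719 to 138187715 on the plus strand (ENSG00000112984), rose 8.84-fold from 7.47 ± 1.04 to 65.9 ± 1.76 CPM. Cyclin A2 (CCNA2) rose 8.35-fold, the spindle gene ASPM 8.92-fold and topoisomerase TOP2A 7.39-fold. Adjusted over the list alone all 30 rose, and the list was higher by camera (median 2.22, adjusted p = 7.57e-110; adjusted p = 0.014 with an estimated correlation). The member short of the threshold over all genes was HMMR (1.22), chosen after its values were seen.

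Of 30 tested DNA replication and G1/S genes 20 rose and 0 fell, and 21 rose adjusted over the list alone (median 0.74, adjusted p = 3.99e-12 by camera; adjusted p = 0.037 with an estimated correlation). The ribonucleotide reductase subunit RRM2 rose by 2.48 ± 0.14 on the log2 scale, the licensing factor CDC6 by 1.39 ± 0.12, the flap endonuclease FEN1 by 1.06 ± 0.10 and the helicase subunit MCM7 by 0.97 ± 0.10. Of 26 tested DNA repair genes 11 rose and 3 fell, with the same numbers adjusted over the list alone, among them FANCA (1.37 ± 0.14), EXO1 (1.78 ± 0.19) and RAD54L (1.79 ± 0.21). The repair list was higher by camera (median 0.23, adjusted p = 0.0119), a call lost at adjusted p = 0.31 with an estimated correlation. Its median was 0.10 without PM2.5 replicate 2 and 0.15 with trends on GC content and length removed. XRCC3 rose by 1.04 ± 0.15, but 76.7% of its exonic bases lie under exons of other genes.

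Of 17 matched replication-dependent histones only 7 passed the filter on low counts, so these need not stand for the whole list. Of the 7 tested 6 fell, also adjusted over the list alone (median -1.20, adjusted p = 2.04e-06 by camera), a call lost at adjusted p = 0.16 with an estimated correlation. HIST1H2BD fell by 1.37 ± 0.19, HIST1H2BK by 1.30 ± 0.13, HIST1H2AC by 1.23 ± 0.12 and HIST1H2BC by 1.20 ± 0.16 on the log2 scale. Histone genes of 1 type resemble one another closely, so the level of each single gene is uncertain. The p53 target list was not called (adjusted p = 0.273 by camera), with 3 of 20 members higher and 5 lower, and 4 and 6 adjusted over the list alone. Its median of 0.13 and mean of -0.11 differ in sign, but the median was -0.02 without PM2.5 replicate 2, 0.22 without PM2.5 replicate 3 and -0.04 with trends on GC content and length removed. The stress cytokine GDF15 fell by 2.78 ± 0.14. The cell cycle inhibitor CDKN1A fell from 1292 ± 81.1 to 765 ± 64.3 CPM and PHLDA3 by 0.85 ± 0.10, while the death receptor TNFRSF10B rose by 0.72 ± 0.09.

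Chaperones of the endoplasmic reticulum rose in the libraries labelled PM2.5, where all 15 tested members were higher, also adjusted over the list alone. HSP90B1 rose 2.91-fold from 1084 ± 230 to 3154 ± 620 CPM (SD, n = 3 each, adjusted p = 2.61e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The disulfide isomerases PDIA4 and PDIA6 rose 2.74-fold and 1.84-fold, and the calcium-binding chaperone calreticulin (CALR) 1.99-fold. The list was higher by camera (median 0.94, adjusted p = 2e-12), a call lost at adjusted p = 0.16 with an estimated correlation. Control replicate 3, the library apart on the second component, held 2919 CPM of HSPA5, the main chaperone of this compartment, against 5641 and 6792 CPM in Control replicates 1 and 2 and 12310 to 13070 CPM in the libraries labelled PM2.5. HSPA5 was chosen after its values were seen. Without Control replicate 3 the list's median was 0.82.

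Of 19 tested ATF4 targets of the integrated stress response 11 rose and 1 fell, and 12 and 2 adjusted over the list alone. The glutathione-degrading enzyme CHAC1 rose by 1.20 ± 0.13 on the log2 scale, the serine synthesis enzyme PSAT1 by 0.72 ± 0.10 and asparagine synthetase (ASNS) by 1.49 ± 0.32 to a mean of 2.33 CPM, while the transcription factor CEBPB fell 2.002-fold. Other genes' exons cover 44.6% of the exonic bases of ASNS. The list was higher by camera (median 0.39, adjusted p = 0.0163), a call lost at adjusted p = 0.38 with an estimated correlation. It was also lost without Control replicate 3, where the median was 0.24. Heat shock proteins as a list were not called (median 0.19, adjusted p = 0.0847 by camera), but were without Control replicate 2 or PM2.5 replicate 3, with limma-voom, with trends on GC content and length removed and by fry (adjusted p = 0.04). Its median was 0.11 without Control replicate 3. In this list 3 of 13 members rose and 0 fell, also adjusted over the list alone: HSP90AA1 by 0.86 ± 0.13, HSPH1 by 0.49 ± 0.12 and DNAJB1 by 0.43 ± 0.10.

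Fibronectin (FN1) rose 2.30-fold from 2681 ± 222 to 6168 ± 301 CPM, the matrix glycoprotein tenascin C (TNC) 4.92-fold from 9.72 ± 0.84 to 47.8 ± 6.98 CPM, and the collagen cross-linking enzyme LOX 2.36-fold from 144 ± 7.88 to 340 ± 5.84 CPM (SD, n = 3 each). The interstitial collagenase MMP1, on chromosome 11 at 102789920 to 102798160 on the minus strand (ENSG00000196611), was the most abundant transcript of the libraries labelled Control and fell from 3.49% ± 0.144 to 1% ± 0.0681 of all counts. Its neighbour stromelysin MMP3, at 102835801 to 102843803 on the minus strand of chromosome 11 (ENSG00000149968), fell 10.7-fold (log2 change -3.41 ± 0.11, SE, adjusted p = 5.31e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and MMP10 rose 4.95-fold.

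Of 22 tested mesenchymal genes 14 rose and 1 fell, and 16 and 1 adjusted over the list alone (median 0.52, adjusted p = 4.49e-08 by camera; adjusted p = 0.037 with an estimated correlation). SPARC rose 4.78-fold, and the member that fell was the transcription factor SNAI2, 4.13-fold from 25.6 ± 4.83 to 6.19 ± 0.91 CPM. Vimentin (VIM) did not pass the test, at 2290 ± 320 and 2683 ± 19.8 CPM. Of 17 tested epithelial junction and keratin genes 7 rose and 0 fell, also adjusted over the list alone, among them keratin KRT18 (0.84 ± 0.10) and the claudins CLDN4 (0.80 ± 0.11), CLDN1 (0.71 ± 0.11) and CLDN7 (0.64 ± 0.10). That list was higher by camera (median 0.38, adjusted p = 0.00898), a call lost at adjusted p = 0.22 with an estimated correlation. E-cadherin (CDH1) had 3 counts over the 6 libraries and was not tested.

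The list of matrix proteases and their inhibitors was not called (median 0.32, adjusted p = 0.795 by camera), with 10 of 22 members higher and 4 lower, and 11 and 4 adjusted over the list alone. The lysosomal protease CTSL was among the falls, by 1.28 ± 0.10 on the log2 scale. Of 18 TGF-beta targets 6 rose and 3 fell, and 7 and 3 adjusted over the list alone (median 0.18, adjusted p = 0.00941 by camera), a call lost at adjusted p = 0.31 with an estimated correlation and also with limma-voom. Without Control replicate 2 the median was 0.11. Connective tissue growth factor (CTGF) rose 6.07-fold, TGFBI 2.35-fold and NEDD9 2.16-fold, and BHLHE40 fell 1.49-fold.

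Of 18 YAP and TEAD targets 6 rose and 1 fell, and 6 and 2 adjusted over the list alone, led by CTGF, which both lists hold, IGFBP3 (1.32 ± 0.10), CRIM1 (1.10 ± 0.09) and AJUBA (0.54 ± 0.10). The list was higher by camera (median 0.12, adjusted p = 0.00028), a call lost at adjusted p = 0.16 with an estimated correlation. The median was 0.19 without Control replicate 3, 0.20 without PM2.5 replicate 2 and 0.25 with trends on GC content and length removed. Breast cancer stem cell genes were not called as a list by camera (median 0.43, adjusted p = 0.273), but were by fry (adjusted p = 0.0088). Of 9 tested 5 rose and 2 fell, and 6 and 2 adjusted over the list alone: integrin ITGA6 rose 2.49-fold, BMI1 1.57-fold, and the aldehyde dehydrogenase ALDH1A3 fell 3.60-fold and the transporter ABCG2 3.09-fold. Other genes' exons cover 28.6% of the exonic bases of ALDH1A3.

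**Figure D4:**
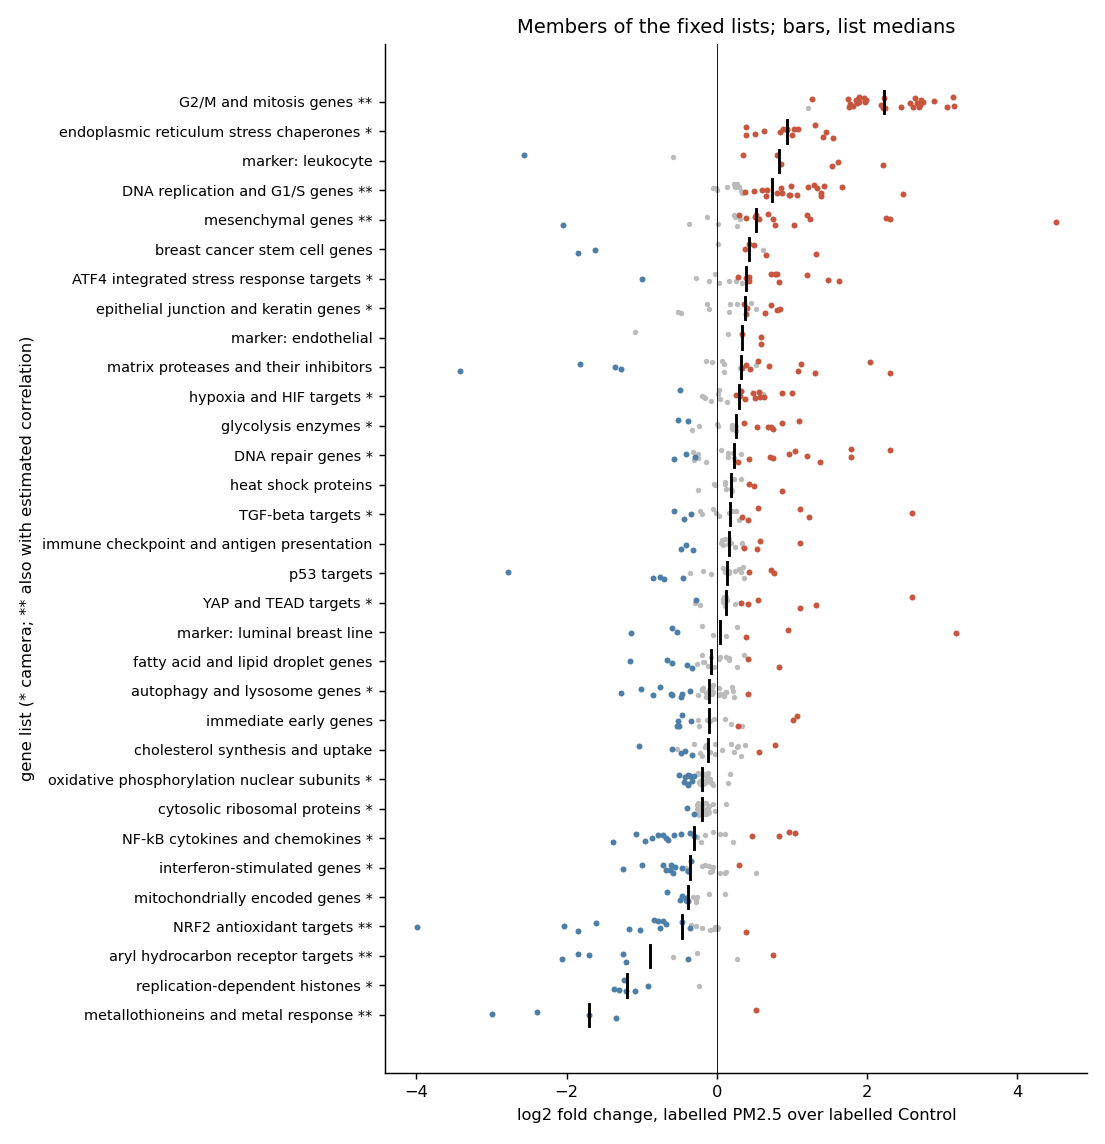
Log2 fold change (labelled PM2.5 over labelled Control, x axis) of each tested member of the 32 gene lists, with points coloured where the adjusted p was under 0.05 and bars at list medians. One asterisk marks lists called by camera and a pair marks the 6 also called with an estimated correlation, from metallothioneins at a median of -1.70 to G2/M genes at 2.22.

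Inflammatory genes moved both ways. Interleukin 1 beta (IL1B) fell 2.60-fold from 975 ± 148 to 375 ± 22.8 CPM and IL1A 1.602-fold from 174 ± 4.22 to 109 ± 3.67 CPM, whereas the neutrophil chemokine CXCL8 rose 1.78-fold from 336 ± 28.4 to 597 ± 19.4 CPM and IL11 1.94-fold from 127 ± 16 to 246 ± 19.3 CPM (SD, n = 3 each). IL6, at 140 ± 20.1 and 126 ± 19.4 CPM, and CXCL1, at 137 ± 33.1 and 140 ± 18.5 CPM, did not pass the test. Of 23 tested NF-kB cytokines and chemokines 4 rose and 12 fell, and 4 and 13 adjusted over the list alone (median -0.30, adjusted p = 0.0119 by camera), a call lost at adjusted p = 0.46 with an estimated correlation. It was also lost without PM2.5 replicate 2, with trends on GC content and length removed and by fry (adjusted p = 0.065). The immune checkpoint ligand CD274 (PD-L1), on chromosome 9 at 5450503 to 5470566 on the plus strand (ENSG00000120217), rose 2.16-fold from 38.6 ± 2.01 to 83.2 ± 5.24 CPM (adjusted p = 3.49e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

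Of 24 tested interferon-stimulated genes 12 fell and 1 rose, also adjusted over the list alone (median -0.36, adjusted p = 0.0023 by camera), a call lost at adjusted p = 0.12 with an estimated correlation. The antiviral GTPases MX1 and MX2 fell by 0.99 ± 0.16 and 1.24 ± 0.21 on the log2 scale, OAS2 by 0.61 ± 0.10 and IFI27 by 0.71 ± 0.13. Immune checkpoint and antigen presentation genes were not called as a list (median 0.16, adjusted p = 0.123 by camera), with 4 of 17 higher and 3 lower, also adjusted over the list alone. The list was called by fry (adjusted p = 0.032) and with trends on GC content and length removed (median 0.27), and its median was 0.10 without Control replicate 3. CD47 and HLA-DRA rose by 0.57 ± 0.10 and 0.53 ± 0.12, and the immunoproteasome subunit PSMB8 fell by 0.42 ± 0.09. Immediate early genes were not called as a list (median -0.11, from -0.21 without Control replicate 3 to -0.03 without Control replicate 2 and 0.07 with those trends removed, adjusted p = 0.635 by camera), with 3 of 16 higher and 5 lower, and 4 and 5 adjusted over the list alone: FOSB and EGR3 rose 2.02-fold and 2.10-fold, and EGR1 and DUSP6 fell 1.44-fold and 1.42-fold. Other genes' exons cover 40.5% of the exonic bases of DUSP6.

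The mitophagy receptor BNIP3 rose 2.003-fold from 282 ± 34.8 to 565 ± 24.8 CPM, and of the glycolytic enzymes phosphoglycerate kinase (PGK1) rose 2.14-fold from 1421 ± 126 to 3034 ± 262 CPM, ENO1 1.67-fold and LDHA 1.61-fold (SD, n = 3 each). Of 21 tested hypoxia and HIF targets 11 rose and 1 fell, also adjusted over the list alone (median 0.30, adjusted p = 0.00659 by camera; adjusted p = 0.31 with an estimated correlation, which ends the call). P4HA1, P4HA2 and ERO1A rose by 0.86 ± 0.09, 0.57 ± 0.09 and 0.62 ± 0.10, and the angiogenic factor VEGFA did not pass the test, at 1994 ± 128 and 1744 ± 69.7 CPM. Of 19 glycolysis enzymes 7 rose and 2 fell, PFKM among the falls, and 9 and 2 adjusted over the list alone (median 0.25, adjusted p = 0.0119 by camera; adjusted p = 0.50 with an estimated correlation, which ends the call). The glycolysis call was also lost without PM2.5 replicate 3.

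Of 30 nuclear subunits of oxidative phosphorylation 10 fell and 0 rose, also adjusted over the list alone (median -0.20, adjusted p = 0.00641 by camera), a call lost at adjusted p = 0.50 with an estimated correlation and by fry (adjusted p = 0.066). NDUFB3 fell by 0.50 ± 0.13 on the log2 scale. Of 13 mitochondrially encoded genes 7 fell and 0 rose, and 10 fell adjusted over the list alone (median -0.38, adjusted p = 0.00281 by camera), a call lost at adjusted p = 0.46 with an estimated correlation. Without Control replicate 3, the library apart on the second component, the median was -0.23. MT-CO1 fell from 9913 ± 724 to 6285 ± 459 CPM (SD, n = 3 each). Cytosolic ribosomal proteins shifted by a median of -0.20 (adjusted p = 0.0101 by camera), a call lost at adjusted p = 0.66 with an estimated correlation, without Control replicate 1 or 2, with trends on GC content and length removed and by fry (adjusted p = 0.21). Without Control replicate 3 the median was -0.31. Of the 34 members RPL13 and RPL19 were called over all genes, both lower, and 0 adjusted over the list alone. Both calls were lost without Control replicate 1 or 2 or PM2.5 replicate 1 or 2, and that of RPL19 also without PM2.5 replicate 3, with DESeq2 size factors and with those trends removed.

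The list of autophagy and lysosome genes was lower by camera (median -0.10, adjusted p = 0.00718), a call lost at adjusted p = 0.46 with an estimated correlation, with 9 of 31 members lower and 1 higher, also adjusted over the list alone. The median was -0.06 without PM2.5 replicate 2, -0.16 without PM2.5 replicate 3 and -0.02 with trends on GC content and length removed. The autophagy receptor SQSTM1, itself an NRF2 target, fell 2.02-fold from 2438 ± 131 to 1209 ± 81.6 CPM, the sialidase NEU1 1.81-fold and ATG7 1.53-fold. Neither lipid list was called by camera, and fry called the fatty acid and lipid droplet list (adjusted p = 0.0088). Of 24 cholesterol genes 2 rose and 5 fell, and 3 and 5 adjusted over the list alone (median -0.12, or -0.05 and -0.03 without Control replicates 1 and 2 and -0.01 with trends on GC content and length removed, adjusted p = 0.573 by camera), with STARD4 higher by 0.77 ± 0.14, while TM7SF2 fell by 1.03 ± 0.14. Of 21 fatty acid and lipid droplet genes 2 rose and 5 fell, and 3 and 5 adjusted over the list alone (median -0.08, or -0.03 and -0.05 without Control replicates 2 and 3, adjusted p = 0.209 by camera). The lipase inhibitor G0S2 fell 2.23-fold, FADS1 1.58-fold and PLIN2 1.51-fold, and HILPDA rose 1.77-fold.

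Markers of other cells were measured alongside. Camera called 0 of their 3 lists, and fry called the luminal (adjusted p = 0.0063) and leukocyte (adjusted p = 0.0093) lists. AGR2, a luminal marker, rose 9.11-fold from 1.29 ± 0.12 to 11.8 ± 1.09 CPM (chromosome 7, 16791811 to 16833433, minus strand, ENSG00000106541), and CA12 rose 1.93-fold, while GREB1 fell 2.20-fold and ERBB2 1.51-fold, so that 3 of 10 luminal markers rose and 3 fell (median 0.04, or -0.01 without Control replicate 1 or PM2.5 replicate 2 and 0.08 without Control replicate 2, adjusted p = 0.273 by camera). Of 8 tested leukocyte markers 6 rose and 1 fell (median 0.83, adjusted p = 0.174 by camera): LYZ was 0.36 ± 0.12 and 1.69 ± 0.24 CPM, CORO1A 2.33 ± 0.41 and 4.204 ± 0.33 CPM, LAPTM5 171 ± 12.6 and 219 ± 11.9 CPM, and FCER1G fell from 1.24 ± 0.07 to 0.21 ± 0.08 CPM. The call of LAPTM5 was lost without PM2.5 replicate 1, and other genes' exons cover 34% of the exonic bases of LYZ. The pan-leukocyte gene PTPRC had 0 counts in all 6 libraries. Of 5 endothelial markers 3 rose and 0 fell (median 0.33, or 0.03 and 0.19 without Control replicates 1 and 2, adjusted p = 0.33 by camera), TIE1 and ROBO4 both by 0.58 ± 0.15. PECAM1 rose by 0.33 ± 0.11, a call lost without Control replicate 1 or 2 or PM2.5 replicate 1 or 3. Adjusted over the list alone, 3 luminal markers rose and 3 fell, 6 leukocyte markers rose and 1 fell, and 3 endothelial markers rose and 1 fell.

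Among protein-coding genes with a mean of at least 2 CPM and no overlap between the groups, the falls were led by the monocarboxylate transporter family member SLC16A6, on chromosome 17 at 68267026 to 68291267 on the minus strand (ENSG00000108932), which fell 29.1-fold from 33.1 ± 10 to 1.14 ± 0.24 CPM (SD, n = 3 each). DUSP15 fell 11.3-fold, the lipase family member PNLIPRP3 5.81-fold, the trypsin inhibitor SPINK1 5.37-fold, XKRX 4.86-fold, CPNE7 4.64-fold and the cytokine IL24 4.47-fold from 868 ± 82.9 to 194 ± 18.8 CPM. Besides mitotic genes such as ANLN (7.59-fold) and KIF18B (7.25-fold), and AGR2 (9.11-fold), the largest rises of such genes were those of NEURL1B (8.40-fold), the cystatin CST1 (8.40-fold, from 17.1 ± 1.59 to 144 ± 18 CPM), FAM72A (7.58-fold), and the desmosomal linker periplakin PPL (7.29-fold). The adhesion protein MPZL2, among the rises with the smallest p-values, rose 7.20-fold. CST1 and FAM72A belong to families of near-identical genes, so their counts are uncertain.

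Camera with the preset correlation called 21 of the 32 lists, 11 higher and 10 lower. With an estimated correlation 6 calls held: G2/M and mitosis, DNA replication and G1/S, mesenchymal, NRF2, aryl hydrocarbon receptor and metallothionein genes. That setting also takes its few degrees of freedom from the libraries, where the preset one takes them from the genes. For interferon-stimulated genes the estimated correlation was 0.01, the preset value, yet the adjusted p by camera moved from 0.0023 to 0.12. A call lost with an estimated correlation is therefore not shown to be lost through genes that vary together. Camera compares a list with all other genes, whereas fry tests whether the list's own genes move on balance one way. Their calls therefore answer different questions. By fry 24 were called: it did not call 3 of the 21 (NF-kB, nuclear oxidative phosphorylation and ribosomal genes) and called 6 others (heat shock, checkpoint, stem cell, fatty acid, luminal and leukocyte genes).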

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

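The trends on GC content and length and the scaling without the 10 most abundant genes were chosen after the data were seen. The number of changed genes was 3245 to 5280 with single libraries left out and 4501 to 5335 under the other settings without a block. Lower genes numbered 1448 (without PM2.5 replicate 1) to 2680 (without Control replicate 3) with single libraries left out, against 2365. Scaling without the 10 most abundant genes and without TMM gave 2001 higher and 2670 lower genes, against 2410 and 2365, so the balance of directions depends on the scaling. Called lists numbered 6 with camera at an estimated correlation, against 21. The cause of these moves was not tested. Replicate numbers did not pair the samples, since same-numbered libraries deviated with correlations of -0.002, -0.051 and -0.122. A replicate block on these numbers gave 3777 changed genes, 1951 higher and 1826 lower, 955 changed at least 2-fold and 21 called lists. Under this block RPL13 (adjusted p = 0.0674) and RPL19 (adjusted p = 0.0952) were not called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Over 149 named genes and 16 settings 2339 values kept direction and side of the threshold, 34 lost it and 2 gained it, and 135 of the 144 called genes kept their call throughout. CXCL1, not called at 0.04, ran from -0.071 to 0.25 with single libraries left out (-0.057, -0.025 and -0.004 without Control replicate 2 and PM2.5 replicates 3 and 1) and was -0.012 without the abundant genes. Of the lists 502 values kept both, 26 lost the call and 11 gained it. In 3 uncalled lists the direction of camera turned. The mean log2 change of the cholesterol list ran from -0.18 to 0.001 with single libraries left out, turning without Control replicate 2. That of the immediate early list ran from -0.098 to 0.046 and was 0.117 with the trends removed. Camera turned to higher without Control replicate 2 and with the trends removed. The mean was also positive without Control replicate 1 (0.03), PM2.5 replicate 1 (0.01) or PM2.5 replicate 2 (0.04), where camera did not turn. That of the protease list ran from 0.117 to 0.201, and camera turned to lower without Control replicate 3 (0.155). The cause was not tested. The fit recovered 35.8% of simulated 1.5-fold changes. It made 141 calls in that simulation, against 4775 in the data, so the adjusted threshold fell there at a smaller unadjusted p. The simulated share therefore does not show how often changes of this size were missed in the data. Some may have been missed, and other depths were not simulated.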

Other observations

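The gene families and non-coding genes described first, and the tests of abundant genes and of leukocytes, were chosen only after the results were seen, and the test of exchanged labels after its pattern was seen. Across 32 gene families looked at, with no test of enrichment, several had called members mostly in 1 direction. Of all 14975 genes tested 31.9% were called, 2410 higher and 2365 lower, so a family's count is to be read beside that share. Of 23 tested collagens 14 were higher in the libraries labelled PM2.5 and 0 lower by edgeR's quasi-likelihood test, with a median log2 change of 0.68: the transmembrane collagen COL13A1 rose by 1.48 ± 0.09 (SE), COL12A1 by 1.13 ± 0.12 and the basement membrane chains COL4A1 and COL4A2 by 0.72 ± 0.09 and 0.90 ± 0.10. Of 21 integrin genes 10 were higher and 2 lower, counting the integrin-like ITGBL1 among the higher. ITGA10 rose by 1.89 ± 0.13 and ITGB4 by 0.97 ± 0.12, while ITGB3 fell by 1.26 ± 0.21. Semaphorins, which guide cell migration, were higher in 7 of 16 and lower in 0, led by SEMA3A (1.11 ± 0.12) and SEMA3C (1.05 ± 0.15). Dual specificity phosphatases were lower in 8 of 19 and higher in 2. DUSP15 fell by 3.5 ± 0.22 and DUSP10 by 0.51 ± 0.09, and DUSP8 rose by 1.08 ± 0.19.

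Of 1448 tested long non-coding genes 166 were higher and 118 lower. The imprinted antisense transcript KCNQ1OT1 rose by 1.88 ± 0.19 (SE) on the log2 scale from 9.58 to 35.4 CPM, and LINC02392 fell by 2.88 ± 0.26 from 13.1 to 1.78 CPM; strand-specific counting is not stated for either. All 8 tested FTH1 pseudogenes were lower, with a median log2 change of -2.16 beside -2.03 for FTH1 itself, so their counts cannot be told from reads of FTH1.

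Targets of the aryl hydrocarbon receptor, NRF2 and metal lists, which particulate matter is known to induce, were lower in the libraries labelled PM2.5, in 22 of their 25 called members. The 10 most abundant genes hold FTL. The median log2 change of the 24 called members outside them was -1.09, and -1.13 with those 10 left out and no TMM. That setting only rescales whole libraries, and the median of all tested genes moved from -0.009 to -0.044 with it. It could not have undone a change this large, so no conclusion is drawn from it. A candidate explanation is that the labels of the groups were exchanged: 11 NRF2 targets outside the lists, picked before their values were seen, had a median of -0.23, just past the -0.2 set beforehand, with 4 lower and 0 higher. This test replaced a first one, the share of called members that were lower (88%), which restates the pattern. A lower activity of these pathways after 48 h of exposure predicts the same and was not tested, so an exchange is a hypothesis that these counts leave open.

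G2/M and mitosis genes were higher in the libraries labelled PM2.5, with a median log2 change of 2.22. It was 2.31 after trends on GC content and gene length were removed, which argues against such trends as the cause. With the 10 most abundant genes left out and no TMM it was 2.18. That setting only rescales whole libraries and could not have undone a rise this large, so no conclusion is drawn from it. The test without the abundant genes replaced a first one, of a like rise of all transcripts of cycling cells. That first test compared the list medians of 2.22 (G2/M) and 0.74 (G1/S), so these lists did not rise by a like amount. An effect of the exposure on proliferation, a difference in culture density and an exchange of labels stay open as untested.

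Some markers of other cell types were higher in the libraries labelled PM2.5. The T cell receptor gene TRAC, chosen after its values were seen, rose by 4.42 CPM, LAPTM5 by 47.4 CPM and LYZ by 1.33 CPM, while PTPRC and TYROBP had 0 counts. Leukocytes stay open as a source, because the summed change of PTPRC, TYROBP and FCER1G, -1.03 CPM, rests on the fall of FCER1G, seen before that test replaced a first one on PTPRC alone. Fibroblasts would bring COL3A1, DCN and LUM with COL1A2, but these rose by 0.058 CPM in sum against 0.528 CPM for COL1A2, and COL1A1, which MDA-MB-231 also expressed, lay at 23.2 and 23.5 CPM. Expression of these genes by the cancer cells themselves was not tested.

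The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The labelled split was the 1 of these 10 with the largest values: it gave 4775 changed genes against at most 0 in the others, 2410 higher and 2365 lower against at most 0, 1081 changed at least 2-fold against at most 0, and 21 called lists against at most 19. Every other split places libraries of both labelled groups on each side, so the labelled difference enters its contrast and its within-group spread. Neither the gene calls nor the list calls of those splits therefore show what chance gives.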
